A study of Mus musculus with 9 samples.

How the data were processed

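RNA sequencing was carried out on aortic tissue from 9 male mice of a mixed 129 and C57BL/6 background, aged 90 days, in 3 groups of 3 libraries. The floxed group carried a loxP-flanked gene for the angiotensin II type 1a receptor (Agtr1a) and no Cre transgene. The Cdh5Cre group carried the same allele with Cre under the promoter of the endothelial cadherin gene Cdh5. The Sm22Cre group carried it with Cre under the promoter of the smooth muscle gene Tagln, also called SM22. Group membership was taken from the titles and the Cre labels of each sample. Per the labels' protocols, RNA was purified from frozen aorta, and preparations with an RNA integrity number above 8 were used. Poly-A RNA was selected from 1 µg of total RNA, stranded libraries were made from fragments of about 300 bp, and paired-end reads of 75 bases were collected on an Illumina HiSeq4000.

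Per the submitters' processing notes, the tools were TopHat2 2.0.8, Bowtie2 2.1.0, SAMtools 0.1.7 and Cufflinks 1.3.0, with the mouse build mm9. The notes used here give no role, order or option for any of them, and the gene annotation is not given in the sources used here. Per the file headers, the deposited table gives 2 FPKM values (fragments scaled to transcript length and to the number mapped) and a status for each gene and each pair of groups. It holds 113004 rows, which are 37668 Ensembl genes in 3 pairs. Each FPKM is the authors' value for a whole group, so the 3 libraries of a group had already been combined. No value per library, fold change, p-value or interval was used here. The depth of the libraries is unknown, because FPKM estimates of this kind are not whole multiples of a read. No SD, standard error, p-value or counting interval could be computed, and every difference between groups has no replicate check. How strand was used in the authors' counting is not given in the sources used here, so genes that overlap on opposite strands may share fragments. Estimates can also be divided among neighbouring or near-identical genes: 6094 of the 14225 genes analysed (42.8%) share their listed locus with another gene.

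Each group's value is listed in 2 pairs. It differed between pairs for 15 genes, with no value above 3.32 FPKM, and 2 of these were among the genes analysed. The Sm22Cre and floxed values were read from the pair of those 2 groups, and the Cdh5Cre value from its pair with Sm22Cre. The status OK was listed for 71.8% of the analysed genes in Cdh5Cre against floxed, 75.6% in Sm22Cre against floxed and 72.0% in Sm22Cre against Cdh5Cre. The status FAIL was listed for 27.7%, 23.8% and 27.4%. Genes with FAIL spread about as widely as genes with OK (SD of the log2 ratios 0.40 and 0.43 in Cdh5Cre against floxed), and both were kept. A similar spread does not show that FAIL estimates are accurate. List results that changed among members with status OK are given with the comparisons. The status HIDATA in any pair removed 7 genes: Acta2, Flna, mt-Co1, mt-Co3, mt-Atp6, mt-Atp8 and mt-Ts1. All but Flna are listed at 0 in every group. Acta2 is a major smooth muscle transcript, so a listed 0 can be a failed estimate and is not read as absence of expression.

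Loci are given on mm9. In 13791 genes the listed end minus the listed start equalled the gene's length in GENCODE M21, against 336 genes for that difference plus 1, so starts were taken to be counted from 0 and 1 was added. GENCODE M21 is on another build and was used only for gene symbols and for transcript length and GC content, never for position. It gave symbols for 32638 of the 37668 genes. Of the 14225 genes analysed, 607 had no symbol, and 12317 (86.6%) had a protein-coding transcript. The longest such transcript gave the gene's length and GC content.

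The log2 ratio of 2 groups was computed on log2(FPKM + 1), which understates differences of low genes. Differences printed as folds are plain ratios of the FPKM values, so for genes near 1 FPKM or below they exceed the ratio on this scale. Genes with 1 FPKM or more in at least 1 of the 3 groups were analysed. The planned tests on single libraries could not be made on group values, so a fixed rule of size was used in their place: a gene was counted as higher or lower when its ratio on this scale reached 2-fold. This rule was set once the table was seen to hold group values alone. The 32 gene lists, 20 of pathways and 12 of cell type markers, were fixed before the data were examined, as was a first set of other settings. Symbols were found for 645 of the 649 list members. For each list the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 99% of them. This describes these group values and is not a test between conditions, since members of a list are not independent of each other. Of 96 list medians, 0.96 would lie outside by chance if genes were independent, and 32 did.

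Named genes are Agtr1a, Cdh5 and Tagln, and in each comparison the 12 genes with the largest log2 ratio in each direction that had 1 FPKM or more in the higher group. Predicted and unnamed genes (symbols such as Gm with digits or ending in Rik, and several families of small RNA) were left out. The rule fixed at first ranked genes that passed a test, and was adapted in this way when no test could be made. For each list discussed, named members are among the 4 with the largest log2 ratios. Other genes are said to have been chosen after their values were seen.

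Because log2 ratios followed transcript length and GC content, a trend-corrected ratio was also computed for the 12317 genes with both. It is the residual of a least-squares fit of the log2 ratio on GC content, log2 length, their squares and their product, with the median added back. This correction, the restriction to genes with status OK, to protein-coding genes or to genes not listed at 0, and a 1.5-fold threshold were chosen after seeing the data. The first set of other settings were pseudocounts of 0.1 and 0.5, no low-value filter, a filter at 5 FPKM, a filter on only the 2 groups compared, median-of-ratios scaling and quantile normalization.

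The calculations were tested on simulated data for Cdh5Cre against floxed. Group values of the 14225 genes were drawn around their means, 200 genes were changed 4-fold, and 99.5% of them were recovered with 0 other genes past 2-fold. The simulated noise was smaller than the spread of the real log2 ratios (SD 0.43), and this count held no length or GC trend. It therefore checks the calculation and not how many real genes pass 2-fold without an effect. A list of 20 genes raised by 0.6 on the log2 scale had a simulated median of 0.60, outside the central 99% of random lists, and an unchanged list lay at percentile 37.9. After a length and GC trend was added and removed again, the rank correlation with length went from -0.77 to 0.01 and the median of the raised list was 0.58. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.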

Results

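The series compared the transcriptome of the mouse aorta with and without the angiotensin II type 1a receptor in endothelial cells or in smooth muscle cells, under a title that names Marfan syndrome, a heritable disorder of the elastic fibre protein fibrillin-1. The labels describe the receptor allele and the Cre transgene of 9 male mice, 3 floxed without Cre, 3 Cdh5Cre and 3 Sm22Cre. All values below are the authors' group values in FPKM, 1 per group. The spread between mice is not known from them and the sequencing depth is unknown, so no difference below could be set against replicate error. The values summed to 495724 FPKM in floxed, 607860 in Cdh5Cre and 500015 in Sm22Cre. The number of genes at 1 FPKM or more was 13683, 13826 and 13721 in the same order. Genes of the mitochondrial chromosome made up 7.07%, 8.88% and 6.38% of these sums, without mt-Co1, mt-Co3, mt-Atp6, mt-Atp8 and mt-Ts1, which are listed at 0 as failed estimates.

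The targeted gene itself was low in all groups. Agtr1a (ENSMUSG00000049115, mm9 chromosome 13, 30428310 to 30474736) stood at 1.75 FPKM in floxed, 1.32 in Cdh5Cre and 1.21 in Sm22Cre. The Cdh5Cre value was 24.6% lower than floxed and the Sm22Cre value 31.1% lower, with log2 ratios of -0.25 and -0.32. Among the 500 genes nearest in expression, these ratios lay at percentiles 20.2 and 6.40, so many genes at this level differed by as much. The value covers the whole gene in whole aorta, and the labels used here do not say which exon is flanked by loxP sites, so a partly retained transcript or receptor in other cells would still count. The labels of the groups are therefore neither borne out nor contradicted by Agtr1a. Its paralogue Agtr1b stood at 0.35, 0.30 and 0.39 FPKM. The genes whose promoters drive Cre were at 13.7, 19.1 and 13.6 FPKM for Cdh5 (ENSMUSG00000031871, chromosome 8, 106625525 to 106668402) and at 4089, 4477 and 4112 FPKM for Tagln (ENSMUSG00000032085, chromosome 9, 45646663 to 45744141). The locus of Tagln is shared with other genes and its status was FAIL in every pair.

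**Figure D1:**
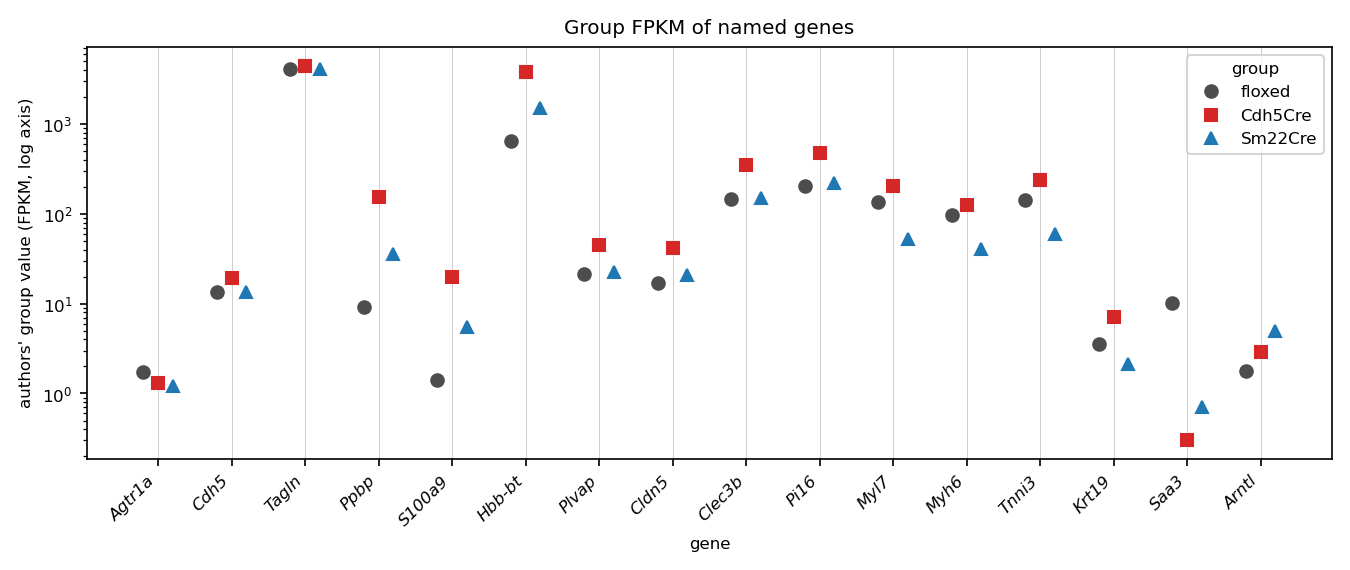
Authors' group values in FPKM (log axis) of 16 named genes, 1 point per group and gene, with no error since each group has a single value. Agtr1a lies between 1.21 and 1.75 FPKM, Ppbp and Hbb-bt are lowest in floxed and highest in Cdh5Cre, and heart muscle genes such as Myl7 are lowest in Sm22Cre.

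The first comparison, Cdh5Cre against floxed, concerned the intended loss of the receptor from endothelial cells. The gene with the highest ratio, Ppbp, which encodes a chemokine of platelets, was 16.8-fold higher (9.12 FPKM in floxed and 153.4 in Cdh5Cre). The platelet genes Clec1b, Gp9 and Tubb1 were 10.3-fold, 9.68-fold and 7.46-fold higher, of which Clec1b shared its listed locus with another gene. S100a8 and S100a9, abundant in neutrophils, were 15.7-fold and 13.9-fold higher. All 6 measured erythroid markers were higher by 2-fold or more, with a median log2 ratio of 2.56. Only 1 of the 6 had status OK, too few to place the list among such members. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt together took 4.18% of the FPKM sum in Cdh5Cre against 0.81% in floxed. These platelet, neutrophil and erythroid genes mark blood cells. No value here tells a different amount of blood in the tissue from an effect of the receptor's loss. Ctla2a and Nrgn, the remaining genes among the 12 with the highest ratios, were 8.13-fold and 7.98-fold higher.

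Endothelial and fibroblast markers were also higher in Cdh5Cre. Of 22 endothelial markers, 20 were higher and 6 reached 2-fold, with a median log2 ratio of 0.55 (interquartile range 0.30 to 0.99). The tight junction gene Cldn5 was 2.44-fold higher (16.9 and 41.3 FPKM), the transcription factor gene Sox18 2.51-fold and the sialomucin gene Emcn 2.30-fold. Of 18 markers of adventitial fibroblasts, 17 were higher, with a median of 0.61. Among them Clec3b was 2.43-fold and Pi16 2.31-fold higher. All 9 measured lymphoid markers were higher (median 0.65), led by the actin-binding protein gene Coro1a at 11.8 and 21.2 FPKM and the kinase gene Lck at 0.29 and 1.20. Schwann cell and neuronal markers had a median of 0.43, with Npy at 2.74 FPKM in floxed and 8.37 in Cdh5Cre, and 16 of 17 heart muscle markers were higher (median 0.55). Macrophage markers (median 0.17) and adipocyte markers (0.06) lay within the range of random lists. The macrophage median was -0.12 with the dependence on transcript length and GC content removed, and the adipocyte median was -0.03 under quantile normalization.

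Among the pathway lists, 19 of 24 immediate early genes were higher (median 0.40), with Ier2 at 15.7 and 39.0 FPKM, Klf2 at 37.4 and 69.5, and Klf6 going the other way at 73.9 and 43.9. The inflammation list had 13 of 17 members higher (median 0.41), although its member with the largest difference, the acute phase gene Saa3, was lower, at a log2 ratio of -3.12 (10.3 and 0.30 FPKM). Il1b was at 0.32 and 1.97 FPKM. The list of vascular tone signalling was the only 1 of the 32 to stand apart as lower: 19 of 24 members were lower, with a median of -0.42. The phosphodiesterase gene Pde3a was 2.42-fold lower, Prkg1, which encodes cGMP-dependent protein kinase, 2.43-fold, and the calcium channel gene Cacna1c 2.30-fold. Smooth muscle contractile genes had a median of -0.04 at percentile 1.74, with Cald1 at 730.1 and 352.3 FPKM and Des higher at 58.1 and 92.4. Elastic fibre genes had a median of 0.33 at percentile 88.6, with 16 of 19 members higher, among them Fbln1 at 141.7 and 247.5 FPKM. Collagens and proteoglycans (median 0.17) lay within the random range and turned to -0.07 under quantile normalization, and TGF-beta signalling genes had a median of 0.01 with 12 of 24 members higher, and of -0.07 under quantile normalization. Genes of the unfolded protein response were higher in 18 of 20 members, with a median of 0.30 at percentile 93.2 and Sdf2l1 at 5.16 and 14.9 FPKM. In all, 9 of 32 lists stood apart, 8 higher and 1 lower, and the medians of the other 23 lay between -0.21 and 0.36. Circadian clock genes (median -0.21) and the mechanical signalling and cytoskeleton list (0.02) stood apart as lower under quantile normalization, at -0.33 and -0.29. Mesothelial and epithelial markers (0.36) stood apart as higher without a low-value filter (0.24).

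After Saa3, the lowest ratios were those of Adnp (4.15-fold), Clec3a (3.37-fold), Pm20d2 (3.87-fold), Lnpep (3.00-fold), Sema5a (2.80-fold) and the BMP receptor gene Bmpr2 (2.84-fold), all lower in Cdh5Cre. Cbl, Pi15, Apol7d and Unc5c followed at 3.10-fold, 2.53-fold, 2.54-fold and 2.72-fold lower. Adnp and Apol7d had status FAIL and shared their listed locus with another gene, and Unc5c, with status OK, shared its locus too. The 5S ribosomal RNA gene n-R5s21 was at 1.57 FPKM in floxed and listed at 0 in Cdh5Cre. Lnpep encodes an aminopeptidase that binds angiotensin IV. It led the renin-angiotensin list, in which 8 of 13 members were lower, with a median of -0.15 at percentile 11.8.

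Of 14225 genes, 169 were higher and 100 lower by 2-fold or more in Cdh5Cre, and 85.7% lay within 1.5-fold. Log2 ratios followed the properties of the transcript. Across 12317 genes, which are not independent replicates, Spearman's rho was -0.58 with transcript length and 0.53 with GC content. The median log2 ratio went from 0.41 in the 10% of genes with the shortest transcripts to -0.37 in the 10% with the longest. Length and GC content together accounted for 44.8% of the variance. With that trend removed, 59 protein-coding genes were higher and 21 lower, against 98 and 63 before, and 54 genes passed 2-fold both ways. Among these lower genes, Lnpep, Sema5a, Bmpr2, Cbl, Pi15 and Unc5c no longer reached 2-fold, while Saa3, Adnp, Clec3a and Pm20d2 did. The list medians became 0.51 for endothelial, 0.56 for fibroblast, 2.09 for erythroid and 0.25 for heart muscle markers, 0.25 for immediate early genes, 0.44 for Schwann cell and neuronal markers and -0.20 for vascular tone signalling, and these 7 lists still stood apart. With the trend removed, 1 of 22 endothelial markers (Emcn) and 1 of 18 fibroblast markers (Pi16) reached 2-fold, against 6 and 4 before. Cldn5 (corrected log2 ratio 0.79), Sox18 (0.82), Clec3b (0.74), Pde3a (-0.65), Prkg1 (-0.64) and Cacna1c (-0.71) did not. The inflammation list (0.18) and the lymphoid list (0.22) no longer stood apart with the trend removed. The inflammation list also no longer did without a low-value filter (0.16) or with the filter at 5 FPKM (0.11), nor did heart muscle markers among members with status OK (0.48) or Schwann cell and neuronal markers with the filter at 5 FPKM (0.36). Elastic fibre genes (0.28), collagens (0.20), the unfolded protein response (0.27), interferon response genes (0.18) and fatty acid synthesis genes (-0.28) stood apart only with the trend removed.

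**Figure D2:**
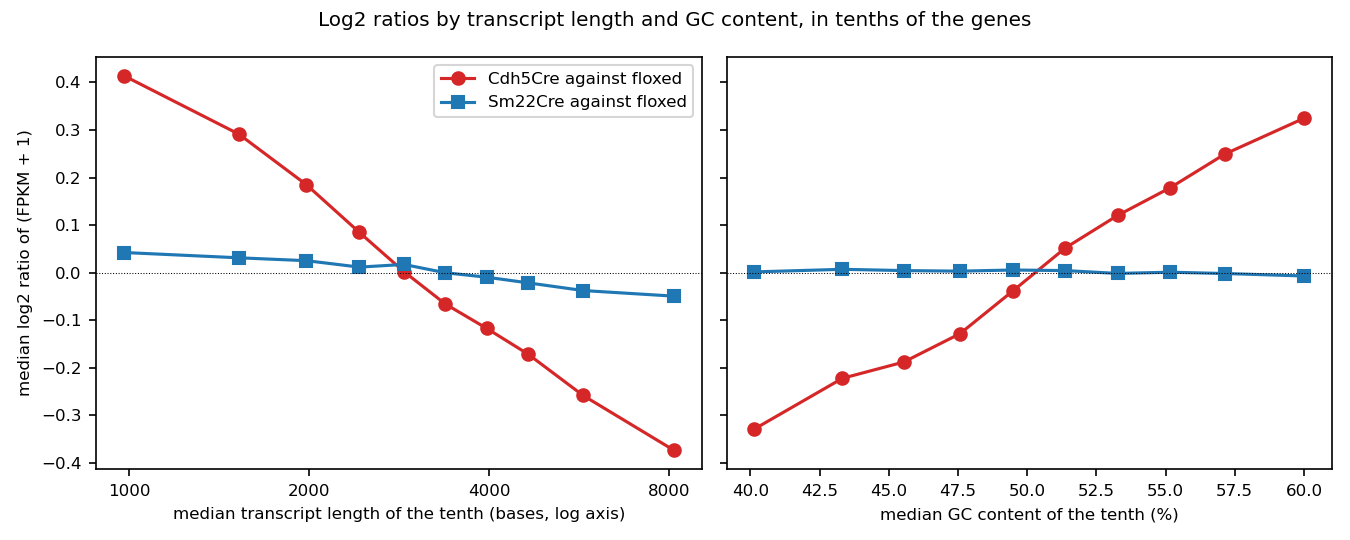
Median log2 ratio of (FPKM + 1) in bins of 10% of 12317 protein-coding genes, ordered by the length of the longest coding transcript (left, bases, log axis) and by its GC content (right, percent). Cdh5Cre against floxed runs from 0.41 to -0.37 with length and from -0.33 to 0.33 with GC content, while Sm22Cre against floxed runs from 0.04 to -0.05 with length and stays within 0.01 of 0 with GC content.

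The second comparison, Sm22Cre against floxed, concerned the intended loss of the receptor from smooth muscle cells. Heart muscle transcripts were lower throughout. All 17 measured heart muscle markers were lower in Sm22Cre, 9 of them by 2-fold or more, with a median log2 ratio of -1.04 (interquartile range -1.20 to -0.92). The atrial myosin light chain genes Myl7 and Myl4 were 2.53-fold and 2.57-fold lower (134.7 and 53.2 FPKM for Myl7), and Myh6 and Tnni3, which encode cardiac myosin heavy chain and cardiac troponin I, were each 2.40-fold lower. Cox6a2, Myl2, Casq2 and Tnnc1, all expressed in striated muscle, were also among the 12 genes with the lowest ratios. Of these named genes, Myl4, Tnni3, Myl2 and Tnnc1 had status FAIL. All of them but Myl7 and Casq2 shared their listed locus with another gene. In the heart muscle list, 13 of the 17 measured markers had status OK. All 8 measured mesothelial and epithelial markers were lower, with a median of -0.40, and Krt19 was at 3.52 and 2.16 FPKM. The list of brown adipocyte markers had a median of -0.10 and 12 of 15 members lower. Its largest differences were in Fabp3, Cox7a1 and Cox8b, which heart muscle also expresses.

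Smooth muscle contractile genes had a median of -0.06, with 16 of 21 members lower. Casq2 and Pln, which are cardiac genes as well, were at 17.4 and 7.08 and at 40.2 and 20.3 FPKM, and Myocd, a coactivator of smooth muscle genes, was at 28.9 and 35.7. The list of TGF-beta signalling also stood apart as lower, with a median of -0.10 and 15 of 24 members lower. Its mean was 0.01, on the other side of 0, and its 4 members with the largest differences, Ccn2, Id1, Id3 and Smad7, were all higher, with Ccn2 at 532.2 and 783.2 FPKM. Clock genes had a median of -0.17. The activators Arntl (2.84-fold, 1.77 and 5.02 FPKM) and Npas2 (2.08-fold) were higher, and Bhlhe41 was 1.74-fold lower. Cholesterol synthesis genes had a median of -0.11, and immediate early genes a median of -0.10, with Fosb at 4.51 and 2.48 FPKM. Genes of the unfolded protein response were higher in 18 of 20 members, with a median of 0.13 and Hspa5, the endoplasmic reticulum chaperone BiP, at 234.3 and 284.4 FPKM. Endothelial markers had a median of 0.10, with 17 of 22 higher and Sox18 at 9.08 and 12.5 FPKM.

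Erythroid markers were higher in Sm22Cre as well, with a median of 1.11 against 2.56 in Cdh5Cre. Of the 6 measured members, 2 had status OK in Sm22Cre against floxed. Lymphoid markers had a median of 0.19. With the trend removed the lymphoid medians were 0.18 in Sm22Cre and 0.22 in Cdh5Cre. Ppbp was 3.96-fold, S100a9 3.84-fold, S100a8 4.10-fold, Clec1b 3.21-fold and Tubb1 2.98-fold higher. Ctla2a, Alas2 and the 4 globin genes made up the rest of the 12 highest ratios together with Arntl. Saa3 had a log2 ratio of -2.73 (10.3 and 0.71 FPKM) and Hal, which encodes histidine ammonia-lyase, of -1.83 (2.77 and 0.06 FPKM). The 5S ribosomal RNA genes n-R5s21 and n-R5s96 were listed at 0 in Sm22Cre.

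Of 14225 genes, 43 were higher and 47 lower by 2-fold or more, and 98.5% lay within 1.5-fold. Of these 90 genes, 48 were listed at 0 in 1 of the groups, so the count rests to a large part on values that can be failed estimates, and 42 genes passed without them. Among protein-coding genes 14 were higher and 21 lower. The dependence on length was smaller than in Cdh5Cre (rho -0.24) and there was little on GC content (rho -0.02). In all, 12 of 32 lists stood apart, 4 higher and 8 lower, all 12 also with the trend removed. Among members with status OK, the smooth muscle contractile list (median -0.06, percentile 1.85) and the clock list (-0.06, percentile 4.74) no longer did. The other 20 medians lay between -0.09 and 0.07. Inflammation genes (median -0.09, percentile 0.59) stood apart with the trend removed (-0.14), with either smaller pseudocount and under quantile normalization. Matrix proteases and inhibitors (0.09) stood apart with the trend removed. Skeletal muscle markers (median -0.04, percentile 12.9) stood apart as lower with the filter at 5 FPKM (-0.38) and among members with status OK (-0.38). Collagens and proteoglycans (-0.05) did so with the filter at 5 FPKM. Of the 12 lists, all but the erythroid, heart muscle and mesothelial lists had medians under 0.2 in size.

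**Figure D3:**
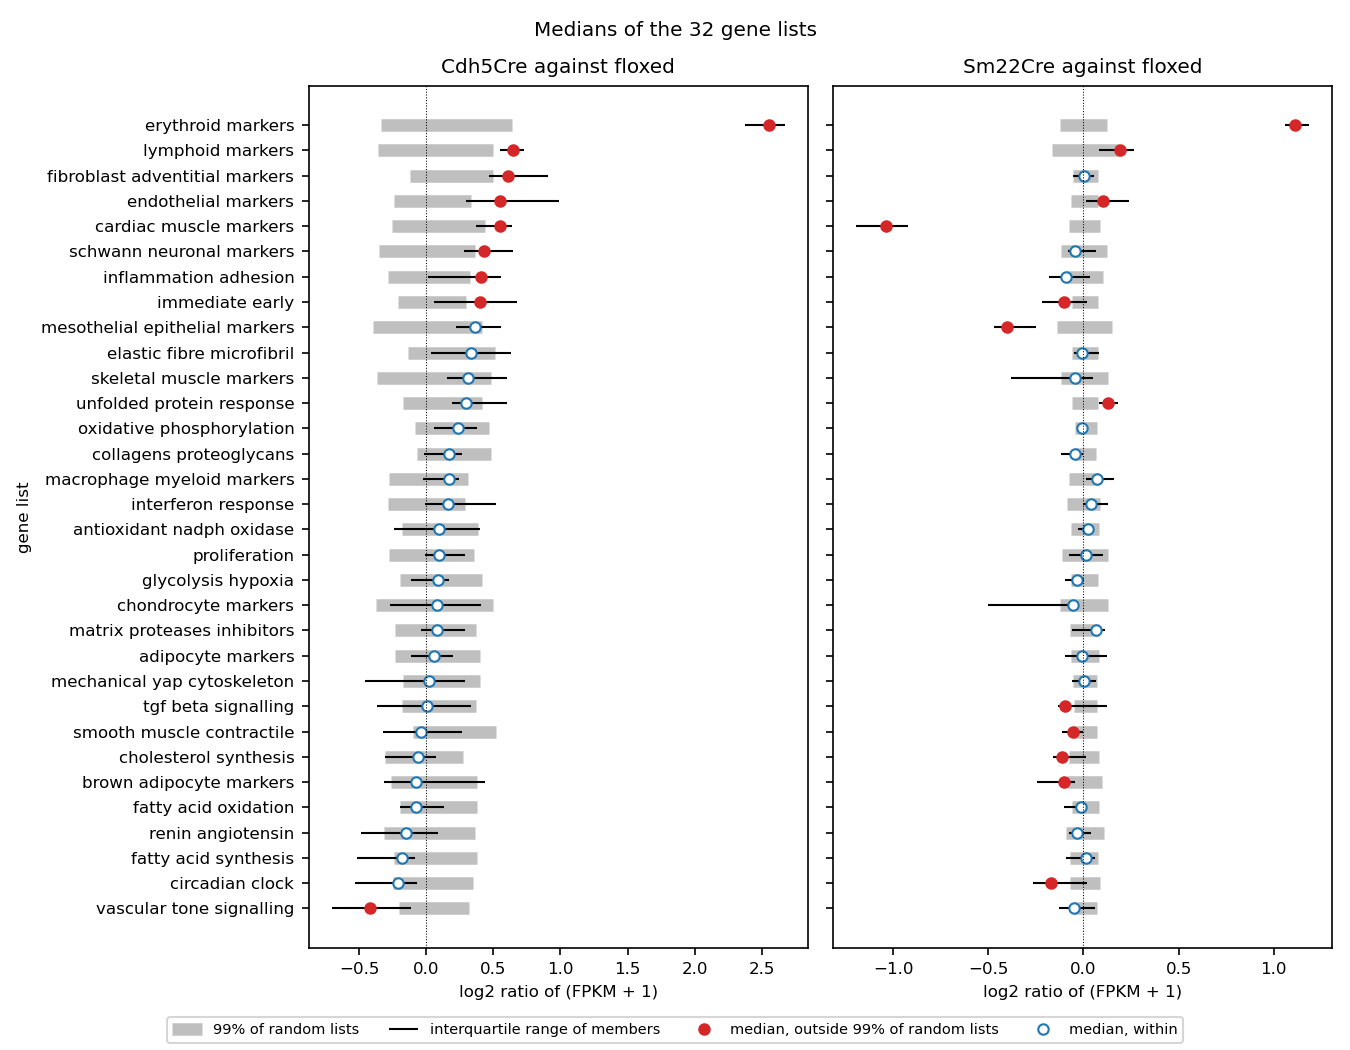
Median log2 ratio of (FPKM + 1) of 32 gene lists in Cdh5Cre against floxed (left) and Sm22Cre against floxed (right). Dots give the medians, black lines the interquartile range of the members and grey bars the central 99% of 10000 random lists matched on expression. Erythroid markers are highest in both (2.56 and 1.11), and heart muscle markers are at 0.55 on the left and -1.04 on the right.

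The third comparison set Sm22Cre directly against Cdh5Cre, without the floxed group. Among the lists, heart muscle markers had the largest median difference, with 16 of 17 lower in Sm22Cre, 14 by 2-fold or more, and a median of -1.55. Myl2 was 4.66-fold, Myl3 3.99-fold and Csrp3, a muscle LIM protein gene, 4.23-fold lower, and Tnni3 was at 240.7 FPKM in Cdh5Cre and 60.2 in Sm22Cre. Myl3 and Tnni3 had status FAIL here. Erythroid markers (median -1.38), mesothelial markers (-0.77), fibroblast markers (-0.67), Schwann cell and neuronal markers (-0.57), lymphoid markers (-0.49), endothelial markers (-0.46), immediate early genes (-0.46) and inflammation genes (-0.34) were lower too. All 18 fibroblast markers were lower in Sm22Cre, with Clec3b at 353.9 FPKM in Cdh5Cre and 151.1 in Sm22Cre. Vascular tone genes were higher in 18 of 24 members (median 0.39), with Pde3a 2.12-fold higher. The mechanical signalling and cytoskeleton list had a median of 0.19 with 12 members higher and 11 lower, among them Ankrd1 at 49.1 and 15.8 FPKM. That median was -0.06 among members with status OK, and it lay within the random range under quantile normalization (0.24).

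Lars2, the mitochondrial leucyl-tRNA synthetase gene, was 4.44-fold lower, Hamp, which encodes the iron hormone hepcidin, 4.83-fold and the muscle creatine kinase gene Ckm 4.32-fold. Ckm is a member of the skeletal muscle list, whose median of -0.21 lay within the random range. Ppbp, Nrgn, Myl7, Myl4 and Tnnc1 were the others among the 12 with the lowest ratios. The highest ratios were those of Lnpep (2.62-fold), Pi15, Apol7d, Adnp, Mamdc4, Arhgap5, Bmpr2, Man1a2, Slc8a1, Lmbrd2, Htr1b and Zfp871, at log2 ratios between 1.09 and 1.32. In this comparison 57 genes were higher and 175 lower by 2-fold or more. The trend was the mirror image of that in Cdh5Cre against floxed, with rho 0.55 for length and -0.58 for GC content. With it removed, 12 protein-coding genes were higher and 78 lower, against 24 and 108 before. Of the genes from Lnpep to Zfp871, Mamdc4 alone still reached 2-fold, and Apol7d had no transcript to correct by. Mamdc4 had status FAIL and shared its listed locus with another gene. Of the 11 lists that stood apart, the lymphoid (-0.04) and vascular tone lists (0.09) no longer did with the trend removed. With the filter at 5 FPKM, neither did the inflammation list (-0.15) nor Schwann cell and neuronal markers (-0.58). The inflammation list lay within the random range under 3 further settings and the lymphoid list under 2. Collagens (-0.23), fatty acid synthesis genes (0.28) and macrophage markers (0.19) stood apart only with the trend removed. Skeletal muscle markers stood apart as lower with the filter at 5 FPKM (-0.91) and among members with status OK (-0.87).

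The differences of both Cre groups from floxed were related across genes, with Pearson's r of 0.36 and Spearman's rho of 0.37 over 14225 genes, which are not independent replicates. Both contrasts share the floxed value, and simulated groups with equal noise and no effect give r = 0.50. That setting gives both contrasts the same variance, which they did not have here, so 0.50 is not a reference for the 0.36. The covariance was 0.030. The noise of the floxed value cannot be estimated from single group values, so no simulated covariance was set beside it and part or all of the relation may come from the shared group. The variance of the log2 ratios was 4.92 times as large in Cdh5Cre as in Sm22Cre. Of the genes past 2-fold, 16 were higher in both contrasts and 20 lower in both. Since both contrasts share the floxed value, some of this overlap would arise without any effect, and its size under no change could not be computed. Of those shared, 12 of the higher and 3 of the lower genes were protein-coding.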

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

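The settings for status, protein-coding genes, genes listed at 0, the length and GC trend and 1.5-fold were chosen after seeing the data. With a pseudocount of 0.1 the genes past 2-fold numbered 586 in Cdh5Cre against floxed (269 as reported), 171 in Sm22Cre against floxed (90) and 528 in Sm22Cre against Cdh5Cre (232), because low genes then count more. A pseudocount of 0.5 gave 349 in the last. A filter at 5 FPKM, which analyses 10208 genes, gave 38 in Sm22Cre against floxed and 149 in Sm22Cre against Cdh5Cre. Protein-coding genes alone gave 161, 35 and 132, and with the trend removed 80, 36 and 90. Leaving out genes listed at 0 gave 42 in Sm22Cre against floxed. At 1.5-fold the counts were 2041, 219 and 1695. The other settings kept the counts within 1.5 times. Agtr1a was lower in both Cre groups under every setting that analysed it, with log2 ratios from -0.38 to -0.25 in Cdh5Cre and from -0.50 to -0.31 in Sm22Cre, but it was not analysed under the filter at 5 FPKM. That direction rests on 1 value per group, which filters leave as it is and pseudocounts cannot turn, so it is not further evidence of a loss. The correlation of the differences of both Cre groups from floxed ranged from 0.36 to 0.41. Across lists and settings, 1003 medians kept their side of the random lists, 21 newly stood apart, 18 no longer did and 1 that stood apart changed sign: the mechanical signalling list in Sm22Cre against Cdh5Cre had a median of -0.0609 when only members with status OK were used, where fewer members enter. Medians of lists that did not stand apart changed sign 43 times. Of the named genes' ratios, 737 kept their side of 2-fold and 17 no longer reached it, and none of them turned. The filters and the restrictions to sets of genes leave a gene's ratio as it was. A smaller pseudocount can only enlarge it. Most of the 737 could therefore not have come out otherwise, and only the scalings and the trend correction could move a named gene below 2-fold. Analyses with single libraries left out, other splits of the samples, the planned limma, camera and fry tests and another adjusted p-value threshold were not run, since each group has 1 value. No paired analysis was possible because the groups share no replicate numbers and the values are per group. Depth limits no statement that can be quantified here, because it is unknown.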

Other observations

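The genes of the next 2 paragraphs were chosen after their values were seen. In floxed and Sm22Cre, Hspa1b, a heat shock gene, was at 51.9 and 106.6 FPKM, Hspa1a at 36.3 and 71.2, Hsph1 at 27.0 and 53.5, Dnaja1 at 67.3 and 97.4 and Hsp90aa1 at 162.9 and 221.8, of which Hspa1b alone reached 2-fold. In Cdh5Cre, Hspa1b was at 81.4, Hspa1a at 55.8, Hsph1 at 31.5, Dnaja1 at 60.7 and Hsp90aa1 at 151.3, while the small heat shock protein gene Hspb1 was at 715.3 FPKM against 198.5 in floxed and 265.3 in Sm22Cre. Nnt, which encodes the mitochondrial transhydrogenase and of which the C57BL/6J strain carries a deleted form, was at 17.7 FPKM in floxed, 10.7 in Cdh5Cre and 9.65 in Sm22Cre. Among the genes of this paragraph, Hspa1a alone had status OK, and the others had FAIL in every pair.

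The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 were at 266.6 and 343.9 FPKM in floxed, 883.5 and 1025 in Cdh5Cre, and 281.3 and 358.6 in Sm22Cre. Lars2 was at 136.7, 363.7 and 81.9 FPKM. Whether its fragments are shared with those genes was not tested. The platelet genes Itga2b and Pf4 were at 4.95 and 26.9 FPKM in floxed, 20.5 and 55.5 in Cdh5Cre, and 8.58 and 31.0 in Sm22Cre.

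Of the tests that follow, only those within the pathway lists were set before their result was seen, and all others were chosen after it. The first pattern is that log2 ratios in Cdh5Cre against floxed were lower for long transcripts and higher for GC-rich ones. A GC-dependent bias of the floxed libraries is argued against by Sm22Cre against floxed, where rho with GC content was -0.0208, but rho with length was -0.24 there, so a floxed part in the length trend stays open. Whole pathways moving together is argued against by the relation within 403 pathway genes, each centred on the median of its list: rho with GC content was 0.48 there (95% bootstrap interval 0.40 to 0.56). Within the same lists rho with length was -0.57 (-0.63 to -0.50), so a length- and GC-dependent bias of the Cdh5Cre libraries, such as in RNA quality or library preparation, is a candidate explanation. Both intervals resample genes, which are not independent replicates, and hold no error between mice or libraries. Whether 1 or all 3 Cdh5Cre libraries carry it, and an effect of the genotype on transcripts by length, stay open and untested.

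The second pattern is the higher level of endothelial and fibroblast markers in Cdh5Cre. The length and GC trend as the whole cause is argued against by the medians with the trend removed, of which the smaller was 0.51. A lower share of smooth muscle alone, with the other cell types in unchanged proportion, would raise the markers of each of them alike. With the trend removed, the fibroblast median instead exceeded that of macrophages by 0.68 (95% bootstrap interval over genes 0.50 to 0.85) and the endothelial median by 0.63 (0.48 to 0.82). These intervals hold no error between mice. A lower share of smooth muscle together with unequal changes of the other cell types stays open. Remaining hypotheses are a larger share of adventitia and endothelium in the dissected Cdh5Cre tissue, or an effect of the genotype. The former would itself lower the share of smooth muscle. No group carried Cre without the floxed allele, so the receptor's loss cannot be told from the Cre transgene itself. No value here separates these hypotheses.

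The third pattern is the lower level of heart muscle markers in Sm22Cre. The length and GC trend is argued against by a median of -1.06 with the trend removed, and a lower level of smooth muscle contractile genes in general by that list's median of -0.0565, which does not address members shared with heart such as Casq2 and Pln. The members had an interquartile range of 0.28 around the median of -1.04. Abundant genes such as Myl7, Tnni3 (status FAIL) and Myh6 were all lower. Ranges were narrow for every list in this comparison, the widest being 0.47 for chondrocyte markers. The narrow range therefore cannot tell less tissue from a joint change of these genes. The values go with less heart muscle, attached at the aortic root, in the Sm22Cre tissue, but do not test it. An effect of the genotype on heart muscle stays open, and without values per library it is not known whether the difference lies in 1 mouse.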
